A study of Mus musculus with 8 samples.

How the data were processed

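Gene expression was measured by stranded sequencing of total RNA, with 75 nt paired-end reads, in 8 libraries of mouse embryonic stem cells, 2 from each of 4 groups. Groups were taken from the sample labels. Per the submitters' processing notes, reads were aligned to mm10 with STAR 2.5.0. The deposited files hold the authors' raw read counts per gene, 1 value per gene and library, with no normalization. The annotation release and the strand setting used for counting are not given in the sources used here. Each file listed 43346 genes, of which 42462 were matched to a symbol and to mm10 coordinates by identifier without its version suffix (23106 with the suffix) and 884 had no symbol. The strand was checked with noncoding genes inside 1 protein-coding gene of more than 5000 counts on average: 215 on the opposite strand had a median of 0.102 counts per kb, against 27.1 for 106 on the same strand. Reads of genes that share exons on 1 strand, or of close paralogs, may be assigned to either. Exon usage, the subject of the series title, cannot be read from counts per gene, and splicing was not analysed here.

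Total counts ranged from 75056306 to 86508533 per library. A count of 3 corresponds to 0.0347 to 0.04 CPM. Loci resembling ribosomal RNA took 2.237 to 4.818% of the counts, the most in wild-type replicate 1. Between the libraries of a group, the chi-square per degree of freedom was 30.73 in wild type, 6.469 in the knockout, 24.16 in the mutant and 10.07 in overexpression, where counting error alone gives 1. Intervals from counting error alone would therefore be too narrow. Abundant loci weigh most in this chi-square. One of them, Gm26917, which resembles ribosomal RNA, took 4.456% and 2.623% of the counts in the wild-type libraries. A high value therefore need not mean that most genes varied widely. The labels do not say whether the libraries of a group come from separate cultures or clones, so the p-values measure only the spread between these libraries. Replicate numbers did not pair libraries across groups: differences between replicates correlated at -0.034 to 0.06 across genes.

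Tests were run in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr at its default minimum count of 10 and total of 15, which left 18055 of 27979 genes with a count. Libraries were scaled by TMM, and 1 quasi-likelihood model with robust dispersions was fitted to all 4 groups with 4 residual degrees of freedom and a biological coefficient of variation of 4.172%. Each of 6 contrasts was tested with edgeR's quasi-likelihood test. All adjusted p-values are Benjamini-Hochberg values, over genes for edgeR and over lists for camera, and a gene or list was called at an adjusted p under 0.05. An exact permutation test of 2 libraries against 2 cannot give a two-sided p below 0.333, so the model, which shares the spread over genes, was used. Levels are TMM-normalized CPM, given as the mean ± SD of 2 libraries.

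Of 29 gene lists written from general knowledge, 27 had at least 5 tested members and were tested with camera on log-CPM with a prior count of 2 and the preset correlation of 0.01. Camera with an estimated correlation and the directional test fry were run beside it. Fry asks whether the members of a list change at all, and camera whether they change more than other genes. Calls were also counted after adjustment over the list alone. Chromosomes were tested as lists, and a chromosome was singled out where its median also lay 0.2 or more from that of all genes. Along every chromosome, in each comparison with wild type, the split that best parted the fold changes was found by least absolute deviation from the medians of both parts. Overlaps and correlations of fold changes were set beside independent calls and beside 40 simulations of unchanged groups, each against a shared pair of simulated wild-type libraries.

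The tests, the lists, the rule for naming genes and most alternatives were set before the data were examined. In each comparison with wild type the rule names the 12 highest and 12 lowest called genes with a mean log2 CPM of at least 1 and both libraries on the same side of both wild-type libraries. It also names Trim71, Mbnl1, Mbnl2 and Mbnl3, up to 4 called members per list, 5 genes per direction in the other contrasts and 8 shared genes, 252 genes in all. Further members of lists are named where a count is 5 or fewer, or where a gene goes against its list or lies on distal chromosome 2, and these were chosen after their values were seen. Called genes without a name of their own were counted and not named: 678 in the knockout, 139 in the mutant and 827 in overexpression.

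The procedure was tested on simulated data with known changes. It recovered 48.6% of 1.25-fold, 60.6% of 1.5-fold, 79.6% of 2-fold and 90.8% of 4-fold changes (500 genes each, over 10 simulations), and 134 of 1532 calls (8.75%) were false, more than the 5% aimed at. Camera called the simulated raised list (adjusted p = 1.12e-08) and 0 of 20 random lists, and a simulated chromosome split after gene 418 was found at gene 405. Genes were simulated independently, so this does not test camera on lists whose members vary together. The estimated correlation of the real lists reached 0.283, for cholesterol synthesis. Alternatives changed the tool (DESeq2 1.42.0), the scaling, the filter, the libraries in the fit, the dispersion method, the genes counted, the fold tested against, a block for replicate number and each library left out in turn.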

Results

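Total RNA of mouse embryonic stem cells, grown without feeder cells on gelatin in serum and LIF, was sequenced on a stranded protocol, and reads were counted per gene in 8 libraries. The cells fell into 4 groups of 2 libraries each. The parental line, which carries an inducible Cre recombinase and a biotin ligase at the Rosa26 locus, is called wild type here. The TRIM71 knockout lacks functional copies of Trim71, which encodes an RNA-binding protein of early embryonic and stem cells. The Mbnl1 3'UTR mutant is homozygous for altered sequence in the 3' untranslated region of Mbnl1, which encodes a regulator of alternative splicing. The Mbnl1 overexpression line was stably transfected with MBNL1 fused through a self-cleaving peptide to puromycin resistance. Total counts were 80640117 and 75056306 in wild type, 86508533 and 82301999 in the knockout, 84387771 and 83859784 in the mutant, and 86336462 and 85068872 in overexpression. Across genes, log-CPM (CPM being counts scaled to a common library total) correlated at 0.995 to 0.997 between libraries of one group and at 0.977 to 0.993 between libraries of different groups.

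The series title names repression of Mbnl1 by TRIM71 and its effect on splicing as the subject, so the mRNA of both genes was read first in each library. Trim71 (ENSMUSG00000079259.2, mm10 chromosome 9, 114507133 to 114564369, minus strand) stood at 630 and 628 CPM in the wild-type libraries and at 101 and 105 CPM in the knockout libraries. This was a fall of 2.61 on the log2 scale (SE 0.036, adjusted p = 2.49e-16, edgeR), and counts per gene do not show which exons the remaining reads came from. It stood at 695 and 694 CPM in the mutant, 1.1-fold above wild type (adjusted p = 0.00832), and at 644 and 667 CPM in overexpression (log2 change 0.06, adjusted p = 0.15, not passing). Mbnl1 (ENSMUSG00000027763.9, chromosome 3, 60472830 to 60629750, plus strand) stood at 25.9 and 26.1 CPM in wild type. It rose 1.92-fold in the knockout, to 49.8 ± 1.45 CPM (mean ± SD, n = 2; log2 change 0.94, SE 0.04, adjusted p = 1.61e-10). In overexpression it rose 7.45-fold, to 194 ± 1.42 CPM (adjusted p = 7.63e-16), with reads of the transgene and the endogenous gene not told apart. The mutant libraries had 28.6 and 27.4 CPM of Mbnl1, a log2 change of 0.11 (SE 0.042) that did not pass (adjusted p = 0.0935). Its relative Mbnl2 fell by 0.37 on the log2 scale in the knockout (adjusted p = 0.0103) and by 0.84 in overexpression (adjusted p = 9.11e-05), and stood at a log2 change of -0.02 in the mutant (adjusted p = 0.908). Mbnl3, at 6.18 ± 0.268 CPM in wild type, did not pass in any of the 3 comparisons with wild type, with log2 changes of 0.18, 0.15 and 0.05.

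**Figure D1:**
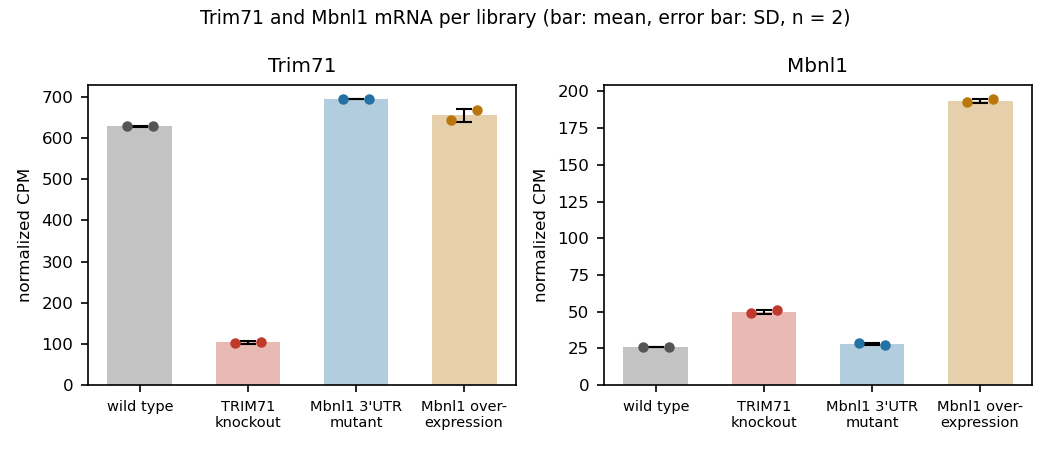
Trim71 (left) and Mbnl1 (right) mRNA in normalized CPM on linear axes from 0. Bars are group means, error bars are the SD of 2 libraries and points are the libraries. Trim71 is lowest in the knockout at 103 CPM, and Mbnl1 is highest in overexpression at 194 CPM.

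The first comparison asks what differs in the transcriptome of the line without TRIM71. Differences between clones cannot be told apart from effects of the knockout. In the knockout, most listed transcripts of naive pluripotency and of cholesterol synthesis were higher, and most of those of formative pluripotency, primitive endoderm and the p53 response were lower. Camera, which compares a list with the other genes, called these 5 lists at its preset correlation, and of the 5 it called the p53 targets alone with an estimated correlation (adjusted p = 0.0394, and 0.26 to 0.458 for the others). Nanog (ENSMUSG00000012396.8, chromosome 6, 122707489 to 122714633), a transcription factor of naive pluripotency, rose 1.92-fold from 312 ± 7.53 to 599 ± 7.11 CPM (n = 2 each). Gata4 and Gata6, transcription factors of primitive endoderm, fell 11.3-fold, from 7.98 ± 0.017 to 0.709 ± 0.0797 CPM, and 9.98-fold, from 3.88 ± 0.446 to 0.386 ± 0.00294 CPM. Among 18055 tested genes, 8092 changed at an adjusted p under 0.05, of which 4352 were higher and 3740 lower. The change was 2-fold or more for 752 of the higher and 605 of the lower genes, and this sum of 1357 fell to 615 with genes under 1 CPM left out.

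The genes with the largest named rises included Vax2, a homeobox gene (log2 change 3.24), Kbtbd11 (8.03-fold), Pof1b (2.69), Slc4a5 (2.68), the calcium channel gene Itpr2 (2.68), B3gnt3 (2.67), Adgrg6 (2.65), Rhox5 (2.54), Tmem108 (2.48), Hal (2.39) and Gpa33 (2.31). H19 rose by 3.19 on the log2 scale (adjusted p = 8.56e-05), although its exons overlap those of another gene on the same strand. Among the largest falls were the endocytic receptor genes Cubn (-4.41) and Lrp2 (-2.15), Srgn (-3.86), the immediate early gene Egr1 (-2.55), the imprinted gene Nnat (-2.52), the homeobox genes Zfhx3 (-2.18) and Meis1 (-2.19), and Dab2 (-2.08). Cubn, Srgn and Dab2 differed between replicates more than most, with standard errors of 0.545, 0.744 and 0.272.

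Of 22 naive pluripotency genes tested, 16 rose, 3 fell (Pecam1, Tcl1 and Fbxo15) and 3 did not pass, and 20 changed when adjusted over the list alone. Klf4 (1.72-fold) and Manba (1.69-fold) rose with Nanog. Camera gave adjusted p = 0.000754, and adjusted p = 0.428 with an estimated correlation. Of 18 formative and primed genes, 13 fell, 2 rose (Tcf15 and Foxd3) and 3 did not pass, with 15 changed when adjusted over the list alone. Pou3f1 fell 2.35-fold, the N-cadherin gene Cdh2 2.26-fold and the DNA methyltransferase gene Dnmt3a 2.2-fold (camera adjusted p = 0.00249, and adjusted p = 0.26 with an estimated correlation). Of 21 primitive endoderm genes, 15 fell, 2 rose and 4 did not pass, with 17 changed when adjusted over the list alone (camera adjusted p = 0.00104, and adjusted p = 0.458 with an estimated correlation). The laminin gene Lamb1 fell 1.86-fold, while Foxa2, a transcription factor of endoderm and of other tissues, rose 4.96-fold from 3.6 ± 0.928 to 17.9 ± 0.173 CPM, and Fst rose too.

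Of 28 p53 targets, 24 fell, Btg2 rose and 3 did not pass, with 25 changed when adjusted over the list alone. The polo-like kinase gene Plk2 fell 2.44-fold, from 58.9 ± 1.92 to 24.1 ± 0.115 CPM, Perp 2.07-fold, Pltp 1.96-fold and Trp53inp1 1.91-fold. Camera gave adjusted p = 1.26e-10, and this call held with an estimated correlation (adjusted p = 0.0394). All 19 cholesterol synthesis genes that changed, of 24 tested, rose, among them Hsd17b7 (1.65-fold), Mvk (1.51-fold), Fdft1 (1.36-fold) and Msmo1 (1.33-fold). Adjusted over the list alone 20 rose, and camera gave adjusted p = 6.6e-06, and adjusted p = 0.428 with an estimated correlation. In the list of ATF4 targets and the unfolded protein response, 17 of 26 genes rose, 4 fell (Sesn2, Ddit4, Ddit3 and Dnajb9) and 5 did not pass, with 22 changed when adjusted over the list alone. Xbp1 rose 2.47-fold, Herpud1 1.66-fold and Atf4 1.27-fold (camera adjusted p = 0.0106, and adjusted p = 0.547 with an estimated correlation).

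Among methylation-sensitive germline genes, 13 of 20 rose, 5 fell (Sycp1, Sycp2, Sycp3, Ddx4 and Tdrd1) and 2 did not pass, with 18 changed when adjusted over the list alone. Rhox6 rose 6.8-fold, Rhox5 5.81-fold and Tex11 2.48-fold (camera adjusted p = 0.0106, and adjusted p = 0.288 with an estimated correlation). Wnt targets fell for 12 of 18 genes, rose for Znrf3, Tcf7 and Notum, and did not pass for 3, with 16 changed when adjusted over the list alone (camera adjusted p = 0.0106, and adjusted p = 0.428 with an estimated correlation). Their fall included genes of low level, such as Wnt3 (0.933 ± 0.0302 to 0.209 ± 0.0313 CPM) and Sp8 (0.876 ± 0.0741 to 0.179 ± 0.0389 CPM), and with genes under 1 CPM left out the camera adjusted p was 0.49. In the neural list 13 of 25 genes fell, among them Gap43 (2.08-fold) and Nefl (1.79-fold), 4 rose (Cntn2, Ncam1, Mapt and Dcx) and 8 did not pass, with 17 changed when adjusted over the list alone. Its camera adjusted p was 0.0421, and adjusted p = 0.458 with an estimated correlation. The neural call was lost with genes under 1 CPM left out (adjusted p = 0.0515) and without wild-type replicate 2 (adjusted p = 0.0866), mutant replicate 1 (0.0597), mutant replicate 2 (0.0598) or chromosome 2 (0.065).

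The remaining lists did not pass camera in the knockout. Of all tested genes 44.8% changed in the knockout, 15.5% in the mutant and 54.8% in overexpression. A count of changed members near that share does not set a list apart from other genes. In the list of TGF-beta and BMP targets 13 of 22 rose and 6 fell (19 adjusted over the list alone), with Lefty2 up 3.48-fold, Inhbb up 2.21-fold, Ccn2 down 2.47-fold and Nodal down 2.01-fold. General pluripotency genes rose for 6 and fell for 10 of 21 (16 adjusted over the list alone), with Lin28a down 1.47-fold. Trophoblast genes rose for 6 and fell for 8 of 14 (14 adjusted over the list alone), with Gata2 up 2.53-fold and Tfap2c up 1.92-fold. Immediate early genes rose for 6 and fell for 13 of 25 (19 adjusted over the list alone), with Spry2 down 1.38-fold and Jund up 1.64-fold. Imprinted genes rose for 7 and fell for 18 of 31 (25 adjusted over the list alone), with Cdkn1c down 1.76-fold and Peg3 up 1.46-fold. Fibroblast and feeder markers rose for 10 and fell for 3 of 18 (14 adjusted over the list alone), with Col6a1 at 3.58 ± 0.24 CPM after a 7.65-fold rise, and this list passed camera with no filter on low counts (adjusted p = 0.0484, and adjusted p = 0.428 with an estimated correlation). Of 40 splicing regulators 6 rose and 11 fell (17 adjusted over the list alone), with Esrp1 up 1.59-fold and Ptbp2 down 1.37-fold.

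Mesendoderm genes rose for 3 and fell for 4 of 14 (7 adjusted over the list alone), let-7 targets for 7 and 7 of 22 (14 adjusted over the list alone), and miR-290 family targets for 4 and 4 of 15 (8 adjusted over the list alone). In the miRNA pathway 4 rose and 8 fell of 17 (12 adjusted over the list alone), and in hypoxia and glycolysis 9 rose and 10 fell of 29 (20 adjusted over the list alone). Cytoskeleton and muscle genes rose for 8 and fell for 5 of 21 (13 adjusted over the list alone), with Acta1 up 5.9-fold. In the cell cycle lists, 9 of 31 genes of the G1/S list rose and 4 fell (13 adjusted over the list alone), and 4 of 22 mitosis genes rose and 3 fell (7 adjusted over the list alone). Ribosomal protein genes rose for 2 and fell for 4 of 46 (4 adjusted over the list alone; 5 rose and 4 fell with library size only), and of 12 mitochondrially encoded genes mt-Nd4 fell (0 adjusted over the list alone). Of 7 reported TRIM71 targets Rbl1 (2.03-fold) and Mbnl1 rose, Egr1, Cdkn1a (1.27-fold) and Ago2 fell and 2 did not pass (5 adjusted over the list alone). Mbnl1 is the subject of the series itself, so this list is not independent evidence of its direction. The lists of 2-cell-like and Y-linked genes had 1 and 2 tested members, too few for camera: Eif1a fell 1.08-fold and 1.22-fold in the knockout and in overexpression, and of the Y-linked genes Uba1y and Eif2s3y fell in the knockout and Eif2s3y rose in overexpression.

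**Figure D2:**
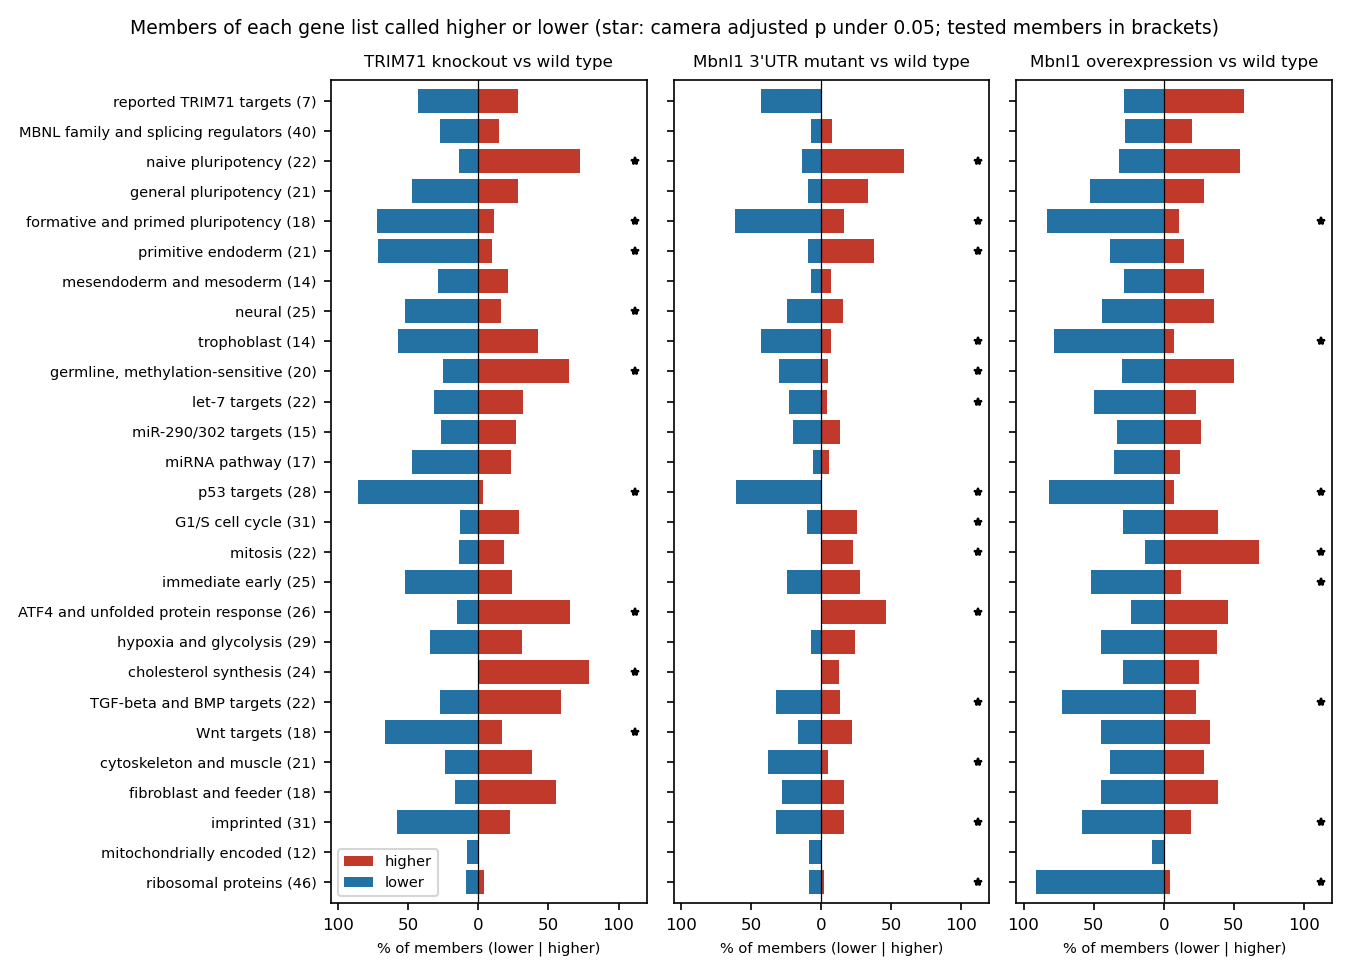
Percent of the tested members of each gene list that were called lower (blue, to the left) or higher (red, to the right) against wild type, with one panel per altered group. Stars mark a camera adjusted p under 0.05 with the preset correlation. The p53 targets fell in every panel, with 24, 17 and 23 of 28 members lower, and ribosomal proteins fell in overexpression, with 42 of 46 members lower.

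The next comparison asks what differs in the line with the altered 3' untranslated region of Mbnl1, where the change of Mbnl1 mRNA did not pass. Differences between clones cannot be told apart from effects of the altered sequence. In the mutant Stmn2, a gene of neuronal microtubules, fell the most of the genes named for this comparison. In the cytoskeleton list 8 of 21 genes fell and in the trophoblast list 6 of 14, while 8 of 21 primitive endoderm and 13 of 22 naive pluripotency genes rose. Camera called these 4 lists at the preset correlation and none of the 4 with an estimated correlation (adjusted p = 0.136 to 0.384). Stmn2 (ENSMUSG00000027500.10, chromosome 3, 8509360 to 8561606) fell by 3.70 on the log2 scale, from 52.5 ± 2.17 to 4.03 ± 0.172 CPM (n = 2 each), and the smooth muscle gene Tagln 5.73-fold, from 9.9 ± 1.03 to 1.73 ± 0.149 CPM. Altogether 2802 of 18055 genes changed, 1448 higher and 1354 lower. Which direction had more depends on the scaling, with 1614 higher and 1262 lower with median-ratio factors and 1186 higher and 1495 lower with library size only. At 2-fold or more 31 were higher and 251 lower, and this sum of 282 fell to 185 without wild-type replicate 1, 163 with DESeq2 and 124 with genes under 1 CPM left out. Without wild-type replicate 1 the number of changed genes was 1768, where the lone wild-type library was assumed to vary like the other groups.

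Beyond these, large falls were seen in Plac8 (-1.97), Thbs1 (-1.94), Slc4a5 (-1.91), Zfp229 (-1.91), Krt18 (-1.63), Fermt1 (-1.61), Itpr2 (-1.57), the noncoding RNA Lncenc1 (-1.47), Acsf3 (-1.47) and Prom1 (-1.27), as log2 changes. Large rises were seen in Pof1b (1.22), Islr2 (1.08), Tbx20 (1.05), Sept1 (1.03), Fignl2 (1.03), Nkx6-3 (1.00), Soga3 (1.00), Irak3 (0.97), Nynrin (0.92), Pou4f2 (0.92), Alpk3 (0.90) and Osbpl10 (0.89). Islr2 and Soga3 share same-strand exons with another gene, which leaves the source of their reads uncertain.

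Primitive endoderm genes rose for 8 of 21 (Lama1, Lamb1, Lamc1, Sparc, Sox7, Pdgfra, Gata4 and Gata6), fell for Foxa2 and Thbd and did not pass for 11, with 10 changed when adjusted over the list alone. Lama1 rose 1.8-fold, from 150 ± 1.7 to 270 ± 28.2 CPM, Sox7 1.85-fold and Lamc1 1.4-fold (camera adjusted p = 0.000652, and adjusted p = 0.384 with an estimated correlation). The list median was 0.4 on the log2 scale. Its 15 members under 20 CPM on average shifted together between replicates, by a median of 0.32 in wild type and 0.26 in the mutant. The rise of the list is therefore not far above the spread between replicates. Naive pluripotency genes rose for 13 of 22, fell for Manba, Pecam1 and Fbxo15 and did not pass for 6, with 17 changed when adjusted over the list alone. Gbx2 rose 1.49-fold, Tbx3 1.46-fold and Klf4 1.44-fold (camera adjusted p = 0.00042, and adjusted p = 0.269 with an estimated correlation). Formative and primed genes fell for 11 of 18, rose for Tcf15, Foxd3 and Sox3 and did not pass for 4, with 16 changed when adjusted over the list alone. The kinase gene Pim2 fell 1.99-fold and Otx2 1.55-fold (camera adjusted p = 0.000652, and adjusted p = 0.136 with an estimated correlation). All 17 p53 targets that changed, of 28, fell, with 22 changed when adjusted over the list alone, among them Plk2 (1.52-fold), Perp (1.37-fold), Eda2r (1.34-fold) and Trp53inp1 (1.34-fold). Their camera adjusted p was 3.51e-09, and adjusted p = 0.052 with an estimated correlation.

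In the cytoskeleton and muscle list 8 of 21 genes fell, Tagln2 rose and 12 did not pass, with 13 changed when adjusted over the list alone. The tropomyosin genes Tpm1 and Tpm2 fell 1.64-fold and 1.56-fold and Cnn2 1.79-fold (camera adjusted p = 0.000892, and adjusted p = 0.136 with an estimated correlation). Trophoblast genes fell for 6 of 14 (Tfap2c, Fgfr2, Phlda2, Krt7, Krt8 and Krt18), rose for Tead4 and did not pass for 7, with 10 changed when adjusted over the list alone. The keratin gene Krt18 fell 3.1-fold and Tfap2c 1.56-fold (camera adjusted p = 0.00333, and adjusted p = 0.269 with an estimated correlation). Of the TGF-beta and BMP targets 7 of 22 fell, 3 rose (Inhbb, Id1 and Smad7) and 12 did not pass, with 13 changed when adjusted over the list alone. Ccn1 fell 1.7-fold and Lefty1 1.47-fold, and Inhbb rose 1.33-fold (camera adjusted p = 0.0184, and adjusted p = 0.242 with an estimated correlation). This call was lost with genes under 1 CPM left out (adjusted p = 0.0954). ATF4 and unfolded protein response genes rose for 12 of 26 and fell for none, with 12 changed when adjusted over the list alone, Chac1 by 1.4-fold and Asns and Atf4 by 1.26-fold each (camera adjusted p = 0.00042, and adjusted p = 0.357 with an estimated correlation).

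Mitosis genes rose for 5 of 22 (Cenpf, Cenpe, Plk1, Mki67 and Top2a; 5 adjusted over the list alone), with camera adjusted p = 0.00818, and adjusted p = 0.423 with an estimated correlation. G1/S genes rose for 8 and fell for 3 of 31 (13 adjusted over the list alone), with Ccnd3 up 1.37-fold and E2f2 up 1.39-fold (camera adjusted p = 0.00995, and adjusted p = 0.423 with an estimated correlation). Germline genes fell for 6 of 20 and rose for Piwil2 (8 adjusted over the list alone), with Rpl10l down 2.23-fold (camera adjusted p = 0.0193, and adjusted p = 0.242 with an estimated correlation). Imprinted genes fell for 10 and rose for 5 of 31 (19 adjusted over the list alone), with Impact down 1.19-fold and Slc38a4 down 1.18-fold (camera adjusted p = 0.0193, and adjusted p = 0.311 with an estimated correlation). Ribosomal protein genes fell for 4 of 46 and rose for Rps16 (3 adjusted over the list alone), at camera adjusted p = 0.0212, and adjusted p = 0.583 with an estimated correlation. The let-7 targets fell for Fign, Arid3a, Hmga2, Mycn and Igf2bp2 of 22 and rose for Cdc25a (8 adjusted over the list alone), with Mycn down 1.31-fold (camera adjusted p = 0.0251, and adjusted p = 0.438 with an estimated correlation). Without 1 of the wild-type or mutant libraries, the highest camera adjusted p was 0.194 for germline genes, 0.134 for let-7 targets, 0.295 for ribosomal proteins, 0.0586 for imprinted genes, 0.0715 for the G1/S cell cycle list and 0.0774 for mitosis. With chromosome 2 left out the let-7 call was lost too (adjusted p = 0.192).

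Not passing camera in the mutant were splicing regulators, with Ptbp3, Srsf4 and Hnrnpa1 up and Ptbp2, Esrp1 and Rbm47 down of 40 (6 adjusted over the list alone; 5 up and 2 down with median-ratio factors, 3 and 4 with library size only), and general pluripotency genes, with 7 up and 2 down of 21 (10 adjusted over the list alone). The same held for neural genes, 4 up and 6 down of 25 (12 adjusted over the list alone), immediate early genes, 7 up and 6 down of 25 (16 adjusted over the list alone), and hypoxia and glycolysis genes, 7 up and 2 down of 29 (9 adjusted over the list alone). Of 24 cholesterol synthesis genes 3 rose, Ebp by 1.24-fold (7 adjusted over the list alone; 6 rose with median-ratio factors and 2 with library size only), at camera adjusted p = 0.0554. This list passed under 9 of the other camera settings (adjusted p = 0.00728 to 0.0446), and had 0.478 without wild-type replicate 2, 0.449 without mutant replicate 2 and 0.612 with an estimated correlation. Hypoxia and glycolysis passed without wild-type replicate 1 (0.0196) or mutant replicate 1 (0.0347), reported TRIM71 targets without mutant replicate 1 (0.0435), splicing regulators without mutant replicate 2 (0.0103), and fibroblast and feeder markers with chromosome 2 left out (0.0183). With an estimated correlation these 4 had adjusted p = 0.423, 0.444, 0.813 and 0.357. Wnt targets rose for 4 and fell for 3 of 18 (7 adjusted over the list alone), with Axin2 up 1.64-fold, and fibroblast and feeder markers rose for 3 and fell for 5 of 18 (10 adjusted over the list alone), with Timp3 down 2.27-fold. Bmp4 (1.58-fold) rose and Wnt3 fell among 14 mesendoderm genes (2 adjusted over the list alone), Rhoc and Nfib rose and Lefty1, Rbl2 and Cdkn1a fell among 15 miR-290 family targets (8 adjusted over the list alone), and Tnrc6c rose and Tut4 fell among 17 miRNA pathway genes (2 adjusted over the list alone). Of 7 reported TRIM71 targets Cdkn1a (1.41-fold), Rbl2 and Egr1 (1.22-fold) fell (4 adjusted over the list alone), and of 12 mitochondrially encoded genes mt-Nd4 fell, at adjusted p = 0.0499 (0 adjusted over the list alone).

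**Figure D3:**
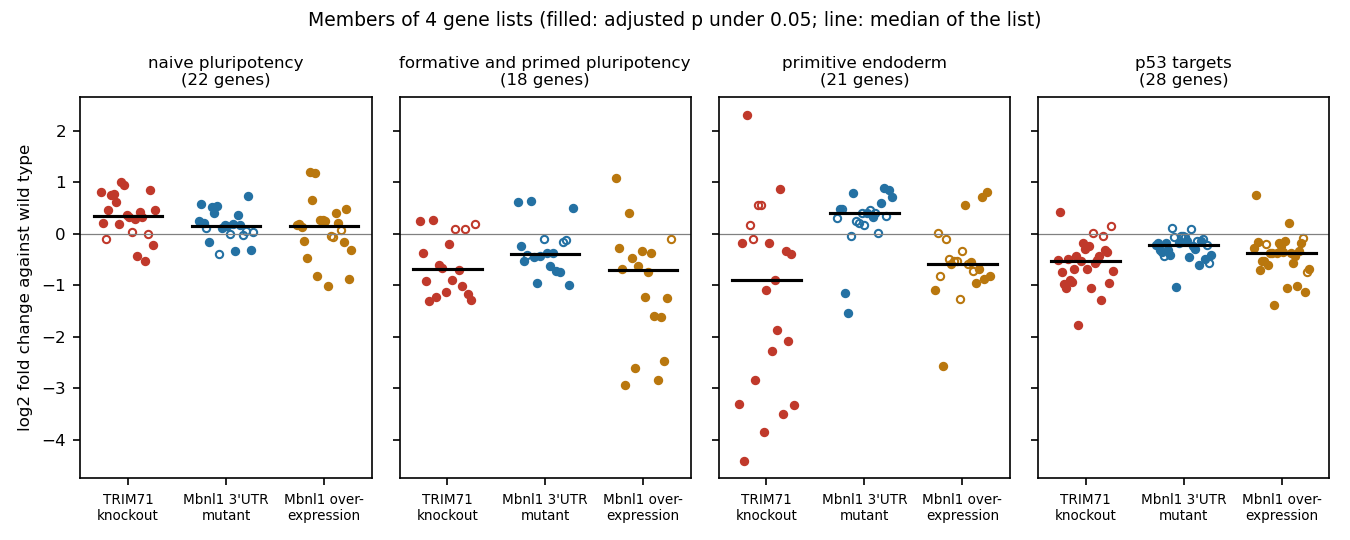
Log2 fold change against wild type of each tested member of the naive pluripotency, formative and primed pluripotency, primitive endoderm and p53 target lists, in columns for the knockout, the mutant and overexpression. Filled points passed at an adjusted p under 0.05, and black lines are list medians. Primitive endoderm genes have a median of -0.90 in the knockout and 0.40 in the mutant.

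The comparison of overexpression with wild type asks what differs in the transfected line, which has a higher level of Mbnl1. The wild-type label names no transfection, and no group was transfected without MBNL1. Effects of Mbnl1 therefore cannot be told apart from those of transfection, selection or differences between clones. In the overexpression line, genes of formative pluripotency, trophoblast, TGF-beta response, imprinted loci and ribosomal proteins were mostly lower, and genes along the distal part of chromosome 2 were mostly higher. Camera called these 5 lists at the preset correlation and none of the 5 with an estimated correlation (adjusted p = 0.102 to 0.385), and the TGF-beta call was also lost with genes under 1 CPM left out. The epithelial splicing factor gene Esrp1 (ENSMUSG00000040728.11, chromosome 4, 11331933 to 11386783) fell 4.18-fold, from 26.2 ± 0.847 to 6.28 ± 0.381 CPM (n = 2 each), and the imprinted noncoding RNA Rian 7.44-fold, from 373 ± 26.6 to 50.1 ± 2.33 CPM. Ribosomal protein genes fell for 42 of 46, by a median of -0.25 on the log2 scale. In all, 9903 of 18055 genes changed, 5006 higher and 4897 lower, against 5763 higher and 4030 lower with library size only. At 2-fold or more 926 were higher and 1098 lower, and this sum of 2024 fell to 1028 with genes under 1 CPM left out.

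On chromosome 2 the median log2 change was 0.32, against -0.01 for all genes, and 70% of its 1498 genes were above 0 (camera adjusted p = 1.19e-07, and adjusted p = 0.0212 with an estimated correlation). The split that best parted the chromosome lay at 71719417, and the 971 tested genes from there to 181870830 had a median of 0.48, against -0.05 for the 527 before it. The split was chosen on these same values, so the step there is not a test, while camera on the whole chromosome does not use it. Of the distal genes 657 rose and 62 fell, and they made up 13.1% of all genes that rose. Both overexpression libraries had a median of 0.48 for these genes over the wild-type mean, and the 4 knockout and mutant libraries lay between -0.01 and 0. Chromosomes X and 13 also passed camera in overexpression, in the other direction and by less. The median of chromosome X lay 0.18 below that of all genes, with 30.7% of 651 genes above 0 (camera adjusted p = 0.000272, and adjusted p = 0.0384 with an estimated correlation), and that of chromosome 13 lay 0.1 below, with 34.1% of 669 above 0 (camera adjusted p = 0.0428, and adjusted p = 0.0314 with an estimated correlation). No other chromosome passed camera in any of the 3 comparisons.

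**Figure D4:**
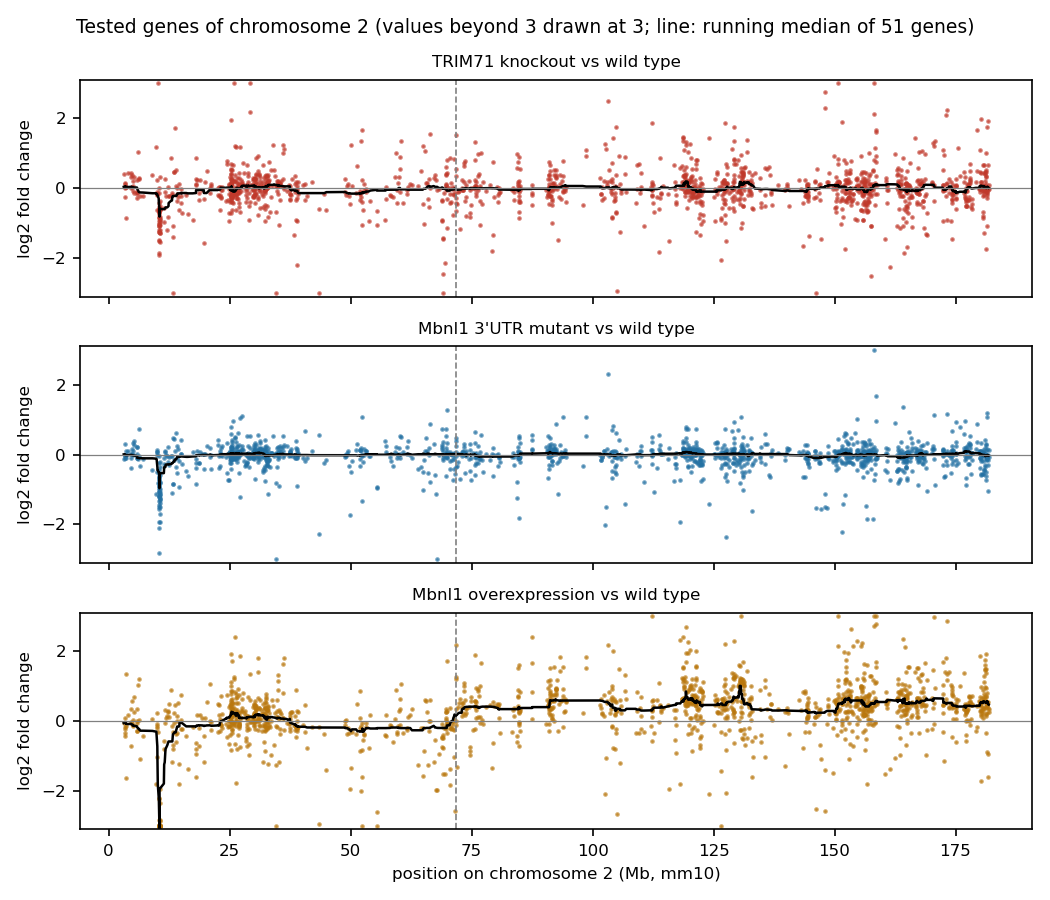
Log2 fold change against wild type of each tested gene of chromosome 2 by its start position in Mb (mm10), with one panel per altered group. Black lines are running medians and the dashed line is the split found in overexpression. Beyond the split the overexpression values have a median of 0.48, and those of the knockout and the mutant have medians of -0.01 and 0.

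Besides Mbnl1, the largest named rises included B3gnt3 (log2 change 3.66), Kbtbd11 (2.95), Islr2 (2.53), Ucp2 (2.36), Rapgef3 (2.24) and Zbtb4 (2.22). Tgm2 (2.72), Nol4l (2.63), Itpka (2.24) and Myh7b (2.22), also among the largest, lie on distal chromosome 2. Large falls were seen in Klhl13 (-3.37), Sema3e (-3.32), Dtna (-3.26), Itpr2 (-3.14), Stmn2 (-3.11), Plac8 (-3.06), Meg3 (-2.95), Fndc3c1 (-2.94), Mirg (-2.94), Lpar4 (-2.90) and Zic2 (-2.84). Meg3, Mirg and Rian are neighbours in the imprinted cluster of chromosome 12 and share same-strand exons with other annotated genes, as does Klhl13.

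Formative and primed genes fell for 15 of 18, rose for Tcf15 and Foxd3 and did not pass for 1, with 17 changed when adjusted over the list alone. Zic2 fell 7.17-fold, Cdh2 5.55-fold and Grhl2 3.08-fold, and Tcf15, on distal chromosome 2, rose 2.13-fold (camera adjusted p = 3.54e-05, and adjusted p = 0.102 with an estimated correlation). Of 28 p53 targets 23 fell, Btg2 and Sesn1 rose and 3 did not pass, with 26 changed when adjusted over the list alone. Perp fell 2.07-fold and Plk2 2.02-fold (camera adjusted p = 1.28e-06, and adjusted p = 0.102 with an estimated correlation). Trophoblast genes fell for 11 of 14 and rose for Tead4, with 12 changed when adjusted over the list alone, Fgfr2 by 5.11-fold, Id2 by 4.12-fold and Tfap2c by 2.23-fold (camera adjusted p = 0.00172, and adjusted p = 0.273 with an estimated correlation). TGF-beta and BMP targets fell for 16 of 22 and rose for Inhbb, Id1, Pmepa1, Smad7 and Ltbp3, with 22 changed when adjusted over the list alone. Ccn2 fell 3.86-fold, Lefty1 2.84-fold and Skil 2.27-fold, and Pmepa1, on distal chromosome 2, rose 2.52-fold (camera adjusted p = 0.00894, and adjusted p = 0.268 with an estimated correlation). This call was lost with genes under 1 CPM left out (adjusted p = 0.0581).

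Imprinted genes fell for 18 of 31, rose for 6 and did not pass for 7, with 24 changed when adjusted over the list alone. The list members Dlk1, Meg3, Rtl1, Rian and Mirg lie in the cluster of chromosome 12 where 62 of 63 tested genes fell, so they are not separate evidence. Of the members Nnat, Nespas and Gnas, on distal chromosome 2, 2 rose. Impact fell 2.58-fold and the cell cycle inhibitor gene Cdkn1c 2.36-fold (camera adjusted p = 0.00524, and adjusted p = 0.273 with an estimated correlation). Immediate early genes fell for 13 of 25 and rose for Btg2, Jund and Ier2 (16 adjusted over the list alone), with Klf6 down 2.92-fold and Dusp4 2.19-fold (camera adjusted p = 0.00781, and adjusted p = 0.434 with an estimated correlation). Ribosomal protein genes other than the 42 that fell were Rpl28 and Rps16, which rose, and 2 that did not pass, with 44 changed when adjusted over the list alone. Rpl22 fell 1.32-fold and Rpl30 1.31-fold (camera adjusted p = 4.08e-08, and adjusted p = 0.385 with an estimated correlation). Mitosis genes rose for 15 of 22 and fell for Cdc20, Kif23 and Ttk (20 adjusted over the list alone), with camera adjusted p = 0.00894, and adjusted p = 0.724 with an estimated correlation. Aurka (1.7-fold), Bub1b (1.57-fold), Tpx2 (1.43-fold), Bub1 (1.42-fold) and Nusap1, 5 of these 15, lie on distal chromosome 2, and with chromosome 2 left out the camera adjusted p of the list was 0.13.

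Of the lists that did not pass camera in overexpression, naive pluripotency had 12 genes up and 7 down of 22 (19 adjusted over the list alone), with Klf4 up 2.3-fold, Tbx3 up 2.25-fold, Klf2 down 2.02-fold and Fbxo15 down 1.83-fold. General pluripotency had 6 up and 11 down of 21 (17 adjusted over the list alone), with Dppa4 down 1.49-fold and Mybl2, on distal chromosome 2, up 1.75-fold. Primitive endoderm had 3 up and 8 down of 21 (11 adjusted over the list alone), with Foxa2 down 5.95-fold although it lies on distal chromosome 2, and Lama1 up 1.75-fold (camera adjusted p = 0.0802, and for primitive endoderm 0.0204 without wild-type replicate 1, 0.035 without overexpression replicate 1, 0.0276 with no filter on low counts and 0.0465 with library size only). Neural genes were up for 9 and down for 11 of 25 (20 adjusted over the list alone), with Gap43 down 6.32-fold. Germline genes were up for 10 and down for 6 of 20 (16 adjusted over the list alone), with Tex11 up 2.73-fold and Ddx4 up 1.61-fold. Splicing regulators were up for 8 and down for 11 of 40 (19 adjusted over the list alone; 12 up and 10 down with library size only), with Ptbp2 down 1.86-fold, and Celf1 (1.29-fold), Rbm38 (1.56-fold) and Srsf6, on distal chromosome 2, up. Fibroblast and feeder markers were up for 7 and down for 8 of 18 (15 adjusted over the list alone), with Timp3 down 4.52-fold, and cytoskeleton and muscle genes up for 6 and down for 8 of 21 (14 adjusted over the list alone), with Tpm1 down 1.8-fold.

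The let-7 targets were up for 5 and down for 11 of 22 (16 adjusted over the list alone), with Ccnd2 down 3.53-fold and Mycn 2.21-fold. Their camera adjusted p was 0.0534, and adjusted p = 0.745 with an estimated correlation, while the list passed under 3 of the other camera settings. ATF4 and unfolded protein response genes were up for 12 and down for 6 of 26 (19 adjusted over the list alone), with Trib3 (2.27-fold), Chac1 (2.17-fold) and Cebpb of those up on distal chromosome 2, and Atf4 itself up 1.42-fold. Hypoxia and glycolysis genes were up for 11 and down for 13 of 29 (24 adjusted over the list alone), with Pfkp up 2-fold and Ldha down 1.26-fold. Cholesterol synthesis genes were up for 6 and down for 7 of 24 (13 adjusted over the list alone; 8 up and 6 down with library size only), G1/S genes up for 12 and down for 9 of 31 (21 adjusted over the list alone), with Ccnd3 up 2.03-fold, and Wnt targets up for 6 and down for 8 of 18 (14 adjusted over the list alone). Members that rose and lie on distal chromosome 2 also include Pcna, E2f1 and Rbl1 of the G1/S list and Gatm and Plagl2 of the let-7 targets. The same holds for Pdk1 (hypoxia and glycolysis), Sycp2 (germline), Fbn1 (fibroblast and feeder), Id1 (TGF-beta and BMP), Sall4 (general pluripotency) and 1 neural gene. Mesendoderm genes were up for 4 and down for 4 of 14 (8 adjusted over the list alone), miR-290 family targets up for 4 and down for 5 of 15 (9 adjusted over the list alone), and miRNA pathway genes up for 2 and down for 6 of 17 (8 adjusted over the list alone; 5 up and 4 down with library size only). Of 12 mitochondrially encoded genes mt-Co1 fell 1.19-fold (0 adjusted over the list alone), and of 7 reported TRIM71 targets Mbnl1, Rbl1, E2f7 and Ago2 rose and Rbl2 and Egr1 fell (6 adjusted over the list alone), with Rbl1 on distal chromosome 2 and Mbnl1 the transfected gene.

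Direct contrasts between the altered groups use no wild-type library. Against the mutant, the knockout had lower Cubn (-4.90), Srgn (-4.27), Gata4 (-4.09), Gata6 (-4.04) and Pdgfra (-3.62) and higher Slc4a5 (4.59), H19 (4.42), Itpr2 (4.25), Stmn2 (3.61) and Foxa2 (3.45), as log2 differences, with 8217 genes differing (4404 higher, 3813 lower). Mbnl1 was 1.78-fold higher and Trim71 6.73-fold lower in the knockout than in the mutant. Against the mutant, overexpression had higher Mbnl1 (2.79), B3gnt3 (2.78), Kbtbd11 (2.75), Tgm2 (2.51) and Acss2 (2.17), the last pair on distal chromosome 2, and lower Pof1b (-3.28), Meg3 (-2.79), Klhl13 (-2.72), Rian (-2.71) and Mirg (-2.68), with 9384 genes differing (4832 higher, 4552 lower). Its Trim71 level differed from that of the mutant by -0.08 (adjusted p = 0.0458), a call lost under most of the 21 other settings, over which the edgeR or DESeq2 adjusted p ran from 0.0326 to 1. Ribosomal protein genes were lower in overexpression than in the mutant for 39 of 46 (camera adjusted p = 6.08e-08, and adjusted p = 0.339 with an estimated correlation). Between knockout and overexpression 9893 genes differed (4962 higher and 4931 lower in the knockout), with Itpr2 (5.82), H19 (5.78), Foxa2 (4.88), Pof1b (4.76) and Klhl13 (4.38) higher in the knockout and Cubn (-3.60), Gata4 (-2.80), Trim71 (-2.67), Wnt6 (-2.64) and Nnat (-2.56) lower. Mbnl1 was 3.89-fold lower in the knockout than in overexpression.

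Genes that changed in the same direction in all 3 comparisons with wild type numbered 585 higher and 491 lower, where independent calls would give 97 and 76. By the size of the smallest change they were led by Plac8 (-1.99, -1.97 and -3.06 in the knockout, mutant and overexpression) and Lncenc1 (-1.44, -1.47 and -2.13), with Pim2 also lower, and by Islr2 (2.07, 1.08 and 2.53), Fignl2 (1.08, 1.03 and 1.92), Nkx6-3 (2.82-fold, 2-fold and 1.91-fold), Sept1 (0.93, 1.03 and 1.87) and Alpk3 (1.01, 0.90 and 1.60). Knockout and mutant shared 715 higher and 600 lower genes, against 349 and 280 for independent calls, and 615 changed in opposite directions, against 626. Knockout and overexpression shared 2270 higher and 1999 lower genes, against 1207 and 1014, with 1318 opposite, against 2217. Mutant and overexpression shared 958 higher and 991 lower genes, against 401 and 367, with 268 opposite, against 768.

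All 3 comparisons use the same 2 wild-type libraries, so part of this excess may come from shared controls. Over all genes the log2 fold changes of knockout and mutant correlated at Pearson r = 0.173 (Spearman 0.231), those of knockout and overexpression at 0.34 (0.38), and those of mutant and overexpression at 0.503 (0.409). The first of these depended on the setting, with r = 0.347 and 0.365 without wild-type replicate 1 and 2, and 0.0317 with genes under 1 CPM left out. Without wild-type replicate 2 the other pairs rose too, to 0.443 and 0.585. A lone shared control adds more common noise, so r rises there by design, and part of r comes from shared controls. Simulated groups with no change, compared with a shared pair of simulated wild-type libraries, gave a mean r of 0.516, 0.524 and 0.524. Real changes add variance and can lower r, so an r below these values does not bound the sharing. The covariance of the fold changes was 0.0461, 0.172 and 0.162, above the highest values of 40 simulations (0.0274, 0.0274 and 0.0271). Each gene had the same dispersion in all simulated groups. Between real libraries the chi-square per degree of freedom ran from 6.469 in the knockout to 30.73 in wild type. It does not settle which group varied the most, since log-CPM correlated less between the mutant libraries (0.99535) than between those of wild type (0.99608). A shift common to both wild-type libraries was not simulated. The simulated shared-control part may therefore be too small, which matters most for 0.0461. The simulated groups shared at most 2 higher genes, but without any change few calls could arise. For contrasts that share no library, knockout against wild type and overexpression against mutant correlated at 0.288 (Spearman 0.294), and overexpression against wild type and knockout against mutant at 0.0173 (0.147). Mutant against wild type and knockout against overexpression correlated at -0.34 (-0.211). These coefficients are across genes, which are not independent replicates.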

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

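All tests in this part that weigh explanations were chosen after the results were seen. A pair of gene lists was called in opposite directions in the knockout and the mutant against wild type. Passing the direct contrast of the groups, which uses no wild-type library, was part of the rule that flagged them. It is therefore not separate support, and a change in either group alone could also give it. Primitive endoderm genes were lower in the knockout than in the mutant for 15 of 21 members and higher for 3 (camera adjusted p = 0.000132, and adjusted p = 0.434 with an estimated correlation). Genes of the list germline, methylation-sensitive were higher for 11 of 20 and lower for 3 (camera adjusted p = 0.00301, and adjusted p = 0.251 with an estimated correlation). The mutant's germline call against wild type was lost without wild-type replicate 2 (adjusted p = 0.194) or mutant replicate 2 (0.0812), and no explanation was tested for this list.

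The fall of primitive endoderm markers in the knockout may come from fewer primitive endoderm-like cells in these libraries or from less transcription within each cell, which cannot be told apart. The 15 markers under 20 CPM differed between replicates together. The median log2 difference of replicate 2 from replicate 1 was 0.32 in wild type, 0.26 in the mutant and -0.24 in overexpression. Of 45 marker and group pairs 35 went with the majority, but genes regulated together would do so in either case. Foxa2 argues against fewer cells for itself, since its log2 change in the knockout was 2.31. A response to Mbnl1 mRNA alone is argued against by the contrast of knockout and overexpression, where the markers had a median of -1.04 although overexpression has the higher Mbnl1 level (camera adjusted p = 0.0178, and adjusted p = 0.605 with an estimated correlation). A difference between clones stays open and was not tested.

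Genes of distal chromosome 2 were higher in overexpression, which may reflect an extra copy of that part in this line. The distal part was delimited on the same overexpression values, so its overexpression medians are not independent of the split. Among 3 classes of expression level the lowest median was 0.44, where 3 copies over 2 would give 0.585, and both libraries had 0.48. A few strongly raised genes cannot carry it, since 80.6% of the 813 genes left without those called at 2-fold or more were above 0. A response in proportion to Mbnl1 mRNA would need a median of 0.16 in the knockout, which had -0.01. DNA was not examined here, and a gain in only some of the cells, or of another size, stays open.

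Of 28 p53 targets 24, 17 and 23 fell in the knockout, mutant and overexpression, and 13 of them fell in all 3 comparisons. With an estimated correlation camera still called the list in the knockout (adjusted p = 0.0394) but not in the mutant (0.052) or overexpression (0.102). A high level in the wild-type libraries alone is argued against for the knockout, where the list was also lower than in the mutant (camera adjusted p = 8.84e-07, and adjusted p = 0.0913 with an estimated correlation). For the mutant, with a median of -0.22, a lower level in the mutant and a higher level in wild type cannot be told apart, because no other altered group had a higher level to compare with. Less Trp53 mRNA is argued against by a log2 change of 0.09 in the knockout (SE 0.033, edgeR adjusted p = 0.0435), and a single wild-type library by medians no higher than -0.20 without either. Differences in culture or passage between the lines could lower the list and were not tested.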

How the results depend on the processing

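Without structural RNA genes and without chromosome 2 genes are alternatives chosen after the data were seen, and the others were set before. No called fold change of a named gene changed sign. The balance of directions did turn with library size only: 1186 genes were higher and 1495 lower in the mutant, and ribosomal protein genes in the knockout (5 and 4) and, in overexpression, splicing regulators, cholesterol synthesis, miRNA pathway and histone genes had more higher than lower members. Of the genes changed in the mutant 51.7% were higher, 48.9% without wild-type replicate 2 and 17.4% against 1.5-fold, and in overexpression 50.6%, with 49.9% with genes under 1 CPM left out and 49.7% without chromosome 2 genes. Over the named genes other than Mbnl1 and Trim71, 8291 combinations of gene, comparison and setting stayed on the same side of the threshold, 259 lost the call and 1 gained it. Mbnl1 and Trim71 are given apart. Mbnl1 rose under all 21 settings, by 0.91 to 0.97 in the knockout and 2.89 to 2.95 in overexpression, and in the mutant it stayed at 0.08 to 0.14, not passing in any. Trim71 in the knockout stayed at -2.63 to -2.57, and the chromosome 2 median of overexpression at 0.22 to 0.36 above that of all genes.

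Tested against a 1.5-fold change, which asks for larger effects by construction, 1160 genes passed in the knockout, 121 in the mutant and 2108 in overexpression, and 1227, 1483 and 2030 in knockout against mutant, overexpression against mutant and knockout against overexpression. Trim71 in the mutant (0.14) no longer passed there. Trim71 in overexpression passed with library size only (0.11, edgeR adjusted p = 0.00963, and 0.00963 to 1 over all settings). The small difference of Trim71 between overexpression and mutant no longer passed at -0.02 with library size only, at -0.07 without chromosome 2 genes, and at -0.08 with only the groups compared, the legacy or non-robust method, without mitochondrial and histone genes, against 1.5-fold, with the replicate block or without structural RNA genes. Leaving out 1 library gave -0.11 to -0.05, none passing. With the replicate block 7899, 2615 and 9766 genes changed in the knockout, mutant and overexpression, and DESeq2 gave 6625, 2290 and 8569.

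Camera called 9, 14 and 8 lists in the knockout, mutant and overexpression. With an estimated correlation, and so with 4 residual degrees of freedom, it called 1, 0 and 0. Fry called 18, 18 and 21, losing 1 of the camera calls, ribosomal proteins in the mutant (adjusted p = 0.16). Fry does not compare a list with other genes, so its calls are not support for those of camera. With genes under 1 CPM left out, changes of 2-fold or more numbered 615, 124 and 1028, against 1357, 282 and 2024. With genes under 1 CPM left out, the correlation of fold changes was 0.0317 for knockout and mutant and 0.281 for knockout and overexpression. The cause was not tested. Leaving out 1 library gave 0.151 to 0.365 for knockout and mutant, 0.311 to 0.443 for knockout and overexpression, and 0.416 to 0.585 for mutant and overexpression, highest without wild-type replicate 2 (in all 3). It gave 1768 to 3163 genes changed in the mutant, lowest without wild-type replicate 1, and 5932 to 8641 in the knockout and 8214 to 10448 in overexpression. A lone library is assumed there to vary like the other groups. Unstranded counts were not run, since each file has 1 count column. Depth limits genes near the floor of 3 counts, and group size limits small changes: 48.6% of the smallest simulated changes and 60.6% of 1.5-fold changes were recovered. Few genes were changed in those simulations, so these shares need not hold for the real data.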

Other observations

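The genes and families in this part were chosen after their values were seen. Ccr4 (ENSMUSG00000047898.6, chromosome 9, 114490316 to 114504916, minus strand), a chemokine receptor gene that starts 2216 bp beyond the end of Trim71 on the same strand, rose from 0.214 ± 0.00226 CPM in wild type (17 and 16 counts) to 97 ± 0.377 CPM in the knockout (log2 change 8.82, SE 0.087, edgeR adjusted p = 3.74e-18). The 16 other tested genes within 500 kb had a median of 0.06, from -0.93 to 2.07. In overexpression, 62 of 63 genes from Dlk1 to Dio3 on chromosome 12 (109452823 to 110281097) fell, with a median of -2.95, and 38 of the 39 microRNA genes among them. In the knockout 17 of the 63 fell (median -0.50) and in the mutant 10 (median -0.36). All 39 microRNA genes within Sfmbt2 on proximal chromosome 2 (10370510 to 10595253) fell in overexpression (median -3.66), 14 in the knockout (-0.84) and 10 in the mutant (-1.09). Sfmbt2 itself changed by -2.83, -1.07 and -0.64 in overexpression, knockout and mutant. Such counts may be intron reads of the host transcript, since noncoding genes on the strand of a host had a median of 27.1 counts per kb against 0.102 on the other strand, so they need not measure separate microRNA genes. The numbers of genes that fell moved by at most 2 under the other scalings.

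Zinc finger genes of distal chromosome 4 fell for 16 of 19 in the knockout (median -0.88) and in overexpression (-0.91), and for 2 in the mutant (-0.10), with 1 higher in overexpression at library size only, and reads of such paralogs are not assigned with certainty. Histone genes rose for 33 of 64 in the knockout and for 11 in the mutant with 4 lower. In overexpression 5 were higher and 15 lower, and 8 and 7 at library size only. Of 70 snoRNA genes 12 fell in the knockout and 21 in overexpression with 1 higher, and their median in the mutant was -0.01. Among DNA methylation genes, Dnmt3l fell in the knockout (-1.92) and overexpression (-1.98) and did not pass in the mutant (-0.21, edgeR adjusted p = 0.13), and Tet2 rose in all 3 (0.87, 0.56 and 0.69). In the order knockout, mutant and overexpression, the log2 changes of the other genes looked at were -0.32, 0.16 and 0.29 for Tet1, 0.1, -0.12 and 0.23 for Tet3, -0.03, 0.29 and 0.08 for Dnmt1, -1.14, -0.1 and -0.33 for Dnmt3a, -0.38, -0.24 and -0.28 for Dnmt3b, and 0.29, 0.26 and 0.14 for Uhrf1. At the end of chromosome 1, 32 of 59 genes fell and 4 rose in overexpression (median -0.47), against medians of -0.07 in the knockout and -0.03 in the mutant. The start of this part was the best split of the same overexpression values, so a step there is not a test. Such splits also parted chromosome 14 (median 0.53 for the first 34 genes and -0.07 after), chromosome 12 (-0.07 and -0.64) and chromosome 15 (-0.18 and 0.13) in overexpression.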
